A study of Mus musculus with 4 samples.

How the data were processed

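Mouse mammary gland cells were transplanted, either as 10000 BC cells alone or as a mixture of 8000 LC and 2000 BC cells, and cells were sorted 3 days later, per the labels' protocols. RNA from 50 sorted cells was extracted for each array with a small-sample kit, and biotin-labelled cDNA was hybridised to an Affymetrix mouse array, per the labels. The sorted population, the animals behind each array and the genome build are not given in the sources used here.

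The deposited values are log2 expression per probe set, 1 column per array, made by the authors with RMA and the affy package, per the submitters' processing notes, which give no versions. RMA corrects background, normalises quantiles across arrays and summarises the probes of a set. The distributions of the 4 deposited columns were not identical, with medians of 4.38, 4.37, 4.38 and 4.62 for BC alone replicates 1 and 2 and control replicates 1 and 2, and interquartile ranges of 2.65, 2.65, 2.60 and 2.03. Whether the 4 arrays were normalised together cannot be read from the values. No detection calls came with them, so a low value is not called absent. No 2 arrays held the same values, the most alike pair having 771 identical values among 45141 probe sets.

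Each of the 45141 probe sets was named from the platform annotation, which is old in part. It gave 28898 probe sets 1 gene symbol and 551 several, and did not name 15692. Through Entrez identifiers 28689 matched the reference gene table, and 0 symbols needed an update. Only probe sets with 1 symbol were named. Each gene was represented by its probe set with the highest mean over all arrays, which left 17097 genes, with no filter on dim probe sets. Among named genes, a dimmer probe set of Als2cl, Cdh3, Csn1s2a, Egfr, Grik3, Gsn, Itgb1, Mmp9, Scara5, Tbx3, Tgfbr2 and Zeb1 had the opposite sign. No coordinates are given, since no build is named for the array's annotation.

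BC alone was compared with the mixture in limma 3.58.1 under R 4.3.3, with lmFit and eBayes on the deposited values, without trend, robust weighting or block, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The fit had 2 residual degrees of freedom, and eBayes estimated 3.50 prior degrees of freedom. A descriptive count took genes with a difference of at least 1 on the log2 scale and no overlap between the groups. Group means carry the SD of 2 arrays and differences the standard error of the fit. A fold is 2 to the power of the log2 difference of RMA values, which compress large differences, and no value was tested against background, so a fold over a dim group may be too small.

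Before the data were examined, 39 gene lists were fixed, with 777 symbols in all, of which 693 were measured, and a few genes belong to more than 1 list. Each was tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 39 lists. Camera asks whether a list differs more than other genes do, and the value given with it is the list's mean log2 difference minus that of all other genes. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, were run beside it, the estimated correlation also, after the results had been seen, without each array, under the other scalings, with the mean of probe sets and without the dimmer genes. Camera with an estimated correlation and fry rest on the 2 residual degrees of freedom of the fit, and on fewer without 1 array. A list that differs could therefore easily fail to pass with them. Single lists were also set against 10000 random lists of the same size matched on expression in 20 bins.

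Genes named in the text follow a rule fixed at the same time. It took the 15 higher and 15 lower genes with the smallest p among those at least 2-fold different without overlap, up to 4 members with the smallest p of each list described, and 12 genes of interest whatever their values, namely Krt5, Krt14, Trp63, Krt8, Krt18, Col1a1, Itgb1, Ddr1, Ptk2, Piezo1, Fos and Jun. Ptk2 had no probe set with a single symbol, so 11 were measured. Which of the 39 lists are described with members, and how many members up to 4, was decided after the results were seen. Acta2, Zeb2, Foxc2, Snai1 and Snai2 in the report and the genes of single arrays in the closing section lie outside this rule and were chosen after their values were seen.

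The fits were tested on data simulated at the spread of these arrays, with 200 of the 17097 genes changed. Of genes changed by 1, 2, 3 and 4 on the log2 scale, 0%, 50%, 98% and 100% were called, and 0.059% of unchanged genes were. Noise was normal, drawn for each gene from its moderated variance, with no deviating array. In the data Cthrc1 differed by 3.13 and had an adjusted p of 0.842 in limma, so these shares may be too high. Camera at the preset correlation called 10 of 10 simulated lists shifted by 1 and 1 of 24 without shifted genes. Simulated genes were independent, while the estimated correlation was 0.35 for the fibrillar collagen list and 0.96 for cytosolic ribosomal proteins. These shares therefore do not carry over to the lists in the data.

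Alternatives were all probe sets, the mean of a gene's probe sets, leaving out the dimmer 50% of genes, another quantile normalization, centring each array on its median, an intensity trend and robust weighting in eBayes, the replicate number as a block, leaving out each array in turn, other thresholds and folds, and camera with an estimated correlation or on ranks, and fry. Cyclic loess normalization was added after the narrower values of control replicate 2 had been seen.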

Results

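Gene expression was measured in mouse mammary gland cells 3 days after transplantation, with microarrays that report RNA as log2 expression values. One group had received 10000 BC cells alone, which the labels call the multipotent condition, and the control group had received 8000 LC cells mixed with 2000 BC cells, called unipotent. BC and LC are usually read as basal and luminal cells in this field, although the labels do not spell them out. Each group had 2 arrays, and RNA for each came from 50 sorted cells. The labels name neither the gate of the sort nor the animals, so p-values measure only the spread between these arrays, which may be technical, and their number limits the precision.

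Basal keratins and contractile genes were far lower on control replicate 2 than on the other 3 arrays. Krt5 had a log2 value of 7.12 there, against 10.76 on control replicate 1 and 10.47 and 10.22 on the BC alone arrays. Acta2, smooth muscle actin, had 6.84 there against 10.29 to 10.68 elsewhere. The values of that array also spanned a narrower range, with an SD over all probe sets of 1.44 against 1.92, 1.92 and 1.90. Its median was 4.62, against 4.38, 4.37 and 4.38. It correlated with the other arrays at a Pearson r of 0.915 to 0.919 over probe sets, which are not independent replicates, while those 3 correlated with each other at 0.968 to 0.972. The bacterial spike-in controls of the array had a median of 9.39 there, against 8.03 and 8.48 on the BC alone arrays and 8.67 on control replicate 1. Many values are therefore also given without control replicate 2.

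**Figure D1:**
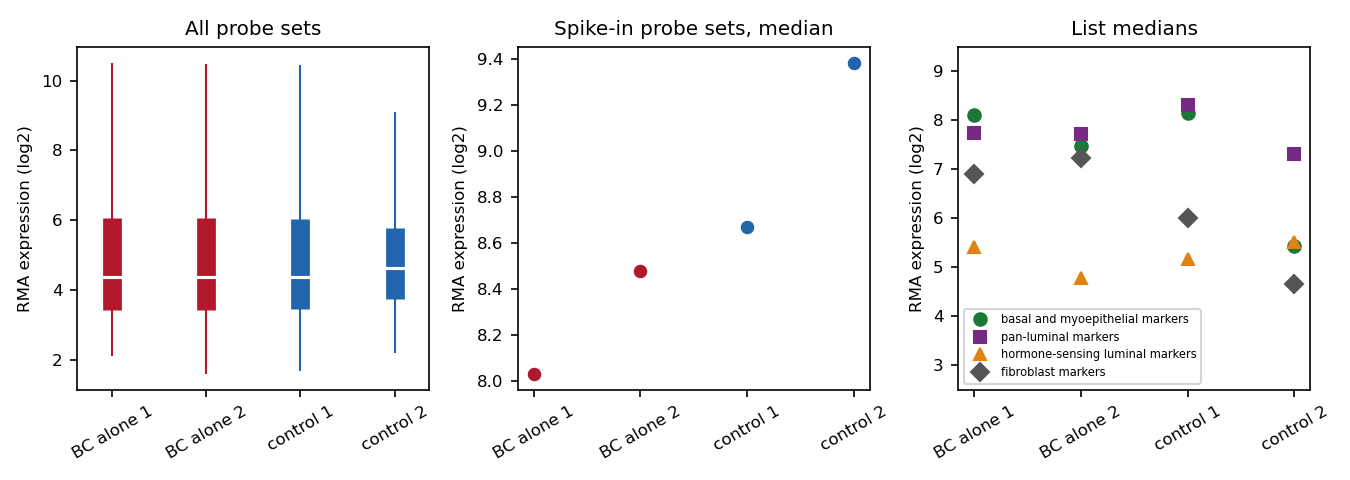
The 4 arrays, BC alone in red and control in blue, on the log2 RMA scale. Left, the line of each array runs from its lowest value to its 99th percentile, the bar covers the quartiles and the white mark is the median. Middle, the median of the 14 spike-in probe sets. Right, medians of 4 gene lists, where the basal list lies at 8.11, 7.48 and 8.15 on the first 3 arrays and at 5.43 on control replicate 2.

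The comparison of BC alone with the mixture asks which genes differ between these transplants, in a study on collagen signalling, matrix stiffness and multipotency. They differ in the presence of LC cells and in the number of BC cells, 10000 against 2000, and these cannot be told apart. Whether LC cells were among the sorted control cells is not stated either. Cthrc1, Ddr2, Fn1 and Cd55 were among the genes higher in BC alone with the smallest p. Cthrc1, a secreted protein of matrix-producing cells, had a log2 value of 7.34 ± 0.45 in BC alone and 4.21 ± 0.06 in the control (SD, n = 2), where it lay below the median of all probe sets and was not tested against background. Ddr2, a receptor for fibrillar collagen, had 8.39 ± 0.26 and 5.96 ± 0.20, a 5.39-fold difference, and Fn1, fibronectin, had 9.34 ± 0.20 and 6.83 ± 0.32, a 5.68-fold difference. A dimmer probe set of Ddr2 differed by 0.53 log2. Cd55, an inhibitor of complement, had 8.06 ± 0.28 in BC alone and 5.10 on both control arrays. Il1b and Mmp13 were among the lower ones. Il1b, the cytokine interleukin-1 beta, had 4.99 ± 0.22 against 6.59 ± 0.19, and the collagenase gene Mmp13 had 2.76 ± 0.19 against 4.66 ± 0.35. In BC alone Mmp13 lay below the median of all probe sets and was not tested against background. Other genes named below also had such a group mean, among them Efemp1, Fgf2, Tek and Fap in the control. In BC alone they included Klf1, Nptx1, Slc1a1 and Ankrd1.

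The other genes among the 15 higher ones with the smallest p were Igfbp6, Fgf2, Efemp1, Scara5, Mxra8, F2r, Dmkn, Cd34, Gucy1a1, Pla1a and Flrt2. Fgf2 is a fibroblast growth factor, Efemp1 an extracellular matrix glycoprotein, F2r a thrombin receptor and Cd34 a surface protein of endothelial and mesenchymal progenitors. Their log2 differences, with those of Cthrc1, Ddr2, Fn1 and Cd55, ran from 1.92 to 3.13. The other genes among the 15 lower ones were Grik3, Cdo1, Slc1a1, Liph, Klf1, Als2cl, Hp, Nptx1, Klk10, Ifitm1, Bcl2a1a, Zfp764 and Il1rn. Il1rn is the antagonist of the interleukin-1 receptor, Klf1 an erythroid transcription factor and Hp haptoglobin. Log2 differences of the 15 lower genes ran from -2.455 for Klk10 to -1.30 for Zfp764. A dimmer probe set pointed the other way for Scara5, Grik3 and Als2cl, at -0.19, 0.93 and 0.19, and the probe set of Bcl2a1a can also bind transcripts of its close paralogs.

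**Figure D2:**
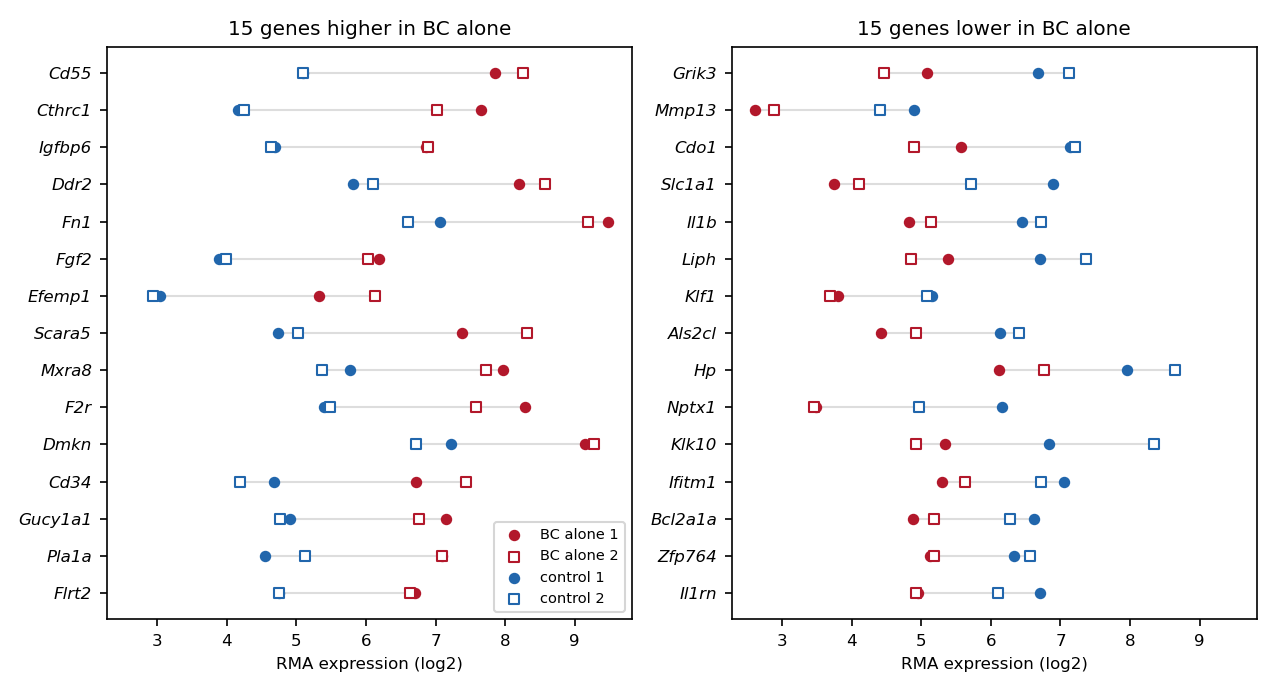
Log2 expression on each array of the 15 genes higher (left) and the 15 lower (right) in BC alone with the smallest p among those at least 2-fold different without overlap. Red marks BC alone and blue the control, filled circles replicate 1 and open squares replicate 2. Cthrc1 lies at 7.66 and 7.02 in BC alone and at 4.17 and 4.25 in the control.

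None of the 17097 genes passed an adjusted p of 0.05 in limma, so the count was 0, and the smallest adjusted p was 0.842. At an unadjusted p under 0.05 there were 680 genes, 527 higher and 153 lower in BC alone, where chance gives 855. With an intensity trend in limma's variance model 97 genes passed, 56 higher and 41 lower, and with a robust variance model 0 did. The 97 included 13 of the 15 higher genes above, all but Fn1 and Dmkn, and 5 of the 15 lower ones, namely Grik3, Mmp13, Slc1a1, Nptx1 and Klk10. An exact permutation test of 2 arrays against 2 cannot go below p = 0.333.

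By size alone, 972 genes differed at least 2-fold with no overlap between the groups, 819 higher and 153 lower in BC alone. Groups did not overlap for 6224 genes, or 36.4%, where chance gives 33.3%. The other ways of splitting the 4 arrays into pairs gave 600 and 659 genes at that size. The excess of higher genes depended on the scaling, since 84.3% of the 972 were higher, against 54.4% of 614 after another quantile normalization, 56.5% of 533 after cyclic loess and 92.0% of 1243 after median centring. Median centring moved the median difference of all genes by 0.125, from -0.04 to 0.09. Without control replicate 2 the count was 732, 375 higher and 357 lower, and 360 genes met the size and direction both ways, 270 higher and 90 lower.

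Fibrillar collagens and the enzymes that process them were higher in BC alone as a group. Of 24 measured members, 21 had a higher mean, and 17 were above both controls on both BC alone arrays. The list median was 8.21 and 7.76 in BC alone, 7.0 on control replicate 1 and 5.5 on control replicate 2. Lox, which crosslinks collagen, had 8.21 ± 0.31 in BC alone and 5.44 ± 1.03 in the control, a 6.82-fold difference (SD, n = 2). Col5a3 had 7.57 ± 0.73 against 5.23 ± 0.41, Loxl1 8.32 ± 0.19 against 6.22 ± 0.95 and Col27a1 7.36 ± 0.40 against 5.95 ± 0.57. Col1a1, a chain of type I collagen, had 10.88 ± 0.05 against 9.46 ± 1.19, and lay at 10.30 on control replicate 1 and 8.62 on control replicate 2. The mean difference of the list exceeded that of the other genes by 1.16 log2 (limma's camera, adjusted p = 1.5e-08, and adjusted p = 0.66 with an estimated correlation). It was 0.57 without control replicate 2 (adjusted p = 7.0e-05) and 1.75 without control replicate 1 (adjusted p = 2.1e-06). Over 14 alternatives, including the replicate block, the adjusted p ran from 5.6e-20 to 0.66. No member passed over all genes, and 2 did adjusted over the list alone.

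Type VI collagen genes and nidogen were also higher in BC alone, among the basement membrane and other collagens. Col6a3 had 9.13 ± 0.16 against 6.26 ± 1.05, Col6a2 9.54 ± 0.13 against 7.26 ± 0.93, Nid1 9.02 ± 0.47 against 7.11 ± 0.68 and Lamb2, a laminin chain, 7.94 ± 0.08 against 6.68 ± 0.27 (SD, n = 2). Of 26 members, 24 had a higher mean, with a relative mean difference of 1.12 (adjusted p = 6.5e-08, and adjusted p = 0.66 with an estimated correlation). Without control replicate 2 only 14 of the 26 were higher, at 0.29 (adjusted p = 0.25), and without control replicate 1 the value was 1.95. Members past the threshold numbered 0 over all genes and 0 adjusted over the list alone.

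Among collagen receptors, integrins and focal adhesion genes, Ddr2 and Ilk, the integrin-linked kinase, were higher in BC alone and Itgb6 was lower. Ilk had 8.47 ± 0.18 against 7.23 ± 0.81, and Itgb6 had 4.92 ± 0.25 against 5.85 ± 0.11 (SD, n = 2). Against control replicate 1 alone Ilk differed by 0.67. Itgb1, the main beta chain of collagen-binding integrins, differed by 0.34 ± 0.34 (SE), Ddr1, an epithelial collagen receptor, by 0.46 ± 0.43 and the stretch-activated channel Piezo1 by 0.07 ± 0.52. The sign of Itgb1, Ddr1 and Piezo1 turned under another quantile normalization and under cyclic loess. Of 26 members, 21 had a higher mean, with a relative mean difference of 0.61 (adjusted p = 2.8e-04, and adjusted p = 0.66 with an estimated correlation). It was 1.07 without control replicate 1 and 0.14 without control replicate 2 (adjusted p = 0.17), and 0.22 and 0.15 under those scalings (adjusted p = 0.08 and 0.17). No member passed over all genes, and 1 did adjusted over the list alone.

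Matrix remodelling genes were divided. Fn1 and Plau, urokinase, were higher in BC alone, with 7.89 ± 0.04 against 6.36 ± 0.71 for Plau, while the metalloproteinase genes Mmp13 and Mmp9 were lower, with 4.14 ± 0.04 against 5.09 ± 0.06 for Mmp9 (SD, n = 2). Of 23 members, 15 had a higher mean, and the relative mean difference was 0.59 (adjusted p = 0.018, and adjusted p = 0.66 with an estimated correlation). It was 0.24 without control replicate 2 (adjusted p = 0.14) and 0.94 without control replicate 1, and the call was also lost under all 3 other scalings, after another quantile normalization at 0.39, after median centring at an unchanged 0.59 (adjusted p = 0.13) and after cyclic loess at 0.31. No member passed over all genes and 2 did adjusted over the list alone. In the epithelial-mesenchymal transition list the transcription factor genes Twist1, Prrx1 and Zeb1 were higher in BC alone, while Zeb2, Foxc2, Snai1 and Snai2 differed by 0.33, 0.25, 0.10 and -0.30. Twist1 had 6.11 ± 0.69 against 4.22 ± 0.11, Prrx1 8.35 ± 0.71 against 6.46 ± 0.80 and Zeb1 6.78 ± 0.64 against 5.49 ± 0.47, or 0.83 higher without BC alone replicate 1. With Fn1, which both lists hold, 11 of 13 members had a higher mean, at 0.84 (adjusted p = 1.9e-04, and adjusted p = 0.66 with an estimated correlation), and at 0.68 without control replicate 2 (adjusted p = 0.13). No member passed over all genes and 2 did adjusted over the list alone.

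Markers of fibroblasts moved with the matrix genes. Thy1 had 8.52 ± 0.18 in BC alone and 6.25 ± 0.46 in the control, Fap 6.13 ± 1.00 and 3.87 ± 0.06, Mfap5 7.04 ± 0.35 and 4.83 ± 1.07, and Gsn 10.35 ± 0.15 and 8.59 ± 0.93 (SD, n = 2). Against control replicate 1 alone Mfap5 and Gsn differed by 1.455 and 1.095. Of 14 members, 13 had a higher mean, at a relative mean difference of 1.33 (adjusted p = 8.2e-08, and adjusted p = 0.66 with an estimated correlation). It was 0.83 without control replicate 2 (adjusted p = 1.6e-04). Over 14 alternatives, including the replicate block, the adjusted p ran from 6.8e-17 to 0.66. Adjusted over the list alone 3 members passed, against 0 over all genes. Fibroblast markers and fibrillar collagens kept their camera call at the preset correlation whichever array was left out, and with an estimated correlation both had adjusted p = 0.565 or more in each of these fits.

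Endothelial markers passed as a list and pericyte markers did not. Tek, the angiopoietin receptor, had 5.62 ± 0.22 against 3.80 ± 0.18, Emcn 6.24 ± 0.57 against 4.93 ± 0.16 and Cdh5 8.22 ± 0.23 against 6.87 ± 0.87 (SD, n = 2), or 0.735 higher than on control replicate 1 alone. Of 15 endothelial markers, 13 had a higher mean, at 0.35 (adjusted p = 0.011, and adjusted p = 0.66 with an estimated correlation). The call was lost without BC alone replicate 1, at 0.20 (adjusted p = 0.22), without control replicate 1, at 0.31 (adjusted p = 0.16), and without the dimmer genes, at 0.07 (adjusted p = 0.67). The pericyte genes Rgs5 and Notch3 had 8.10 ± 0.44 against 5.10 ± 0.92 and 8.64 ± 0.79 against 7.0 ± 0.08. The 6 pericyte markers did not pass, at 0.72 (adjusted p = 0.053), and passed without control replicate 2, at 1.08 (adjusted p = 0.027), BC alone replicate 1, at 0.66 (0.020), or BC alone replicate 2, at 0.78 (0.013), and with the mean of a gene's probe sets, at 0.67 (0.041), each with adjusted p = 0.607 or more with an estimated correlation. Without control replicate 1 they gave 0.36 (adjusted p = 0.91). Adjusted over the list alone, 1 endothelial and 2 pericyte markers passed, against 0 over all genes.

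**Figure D3:**
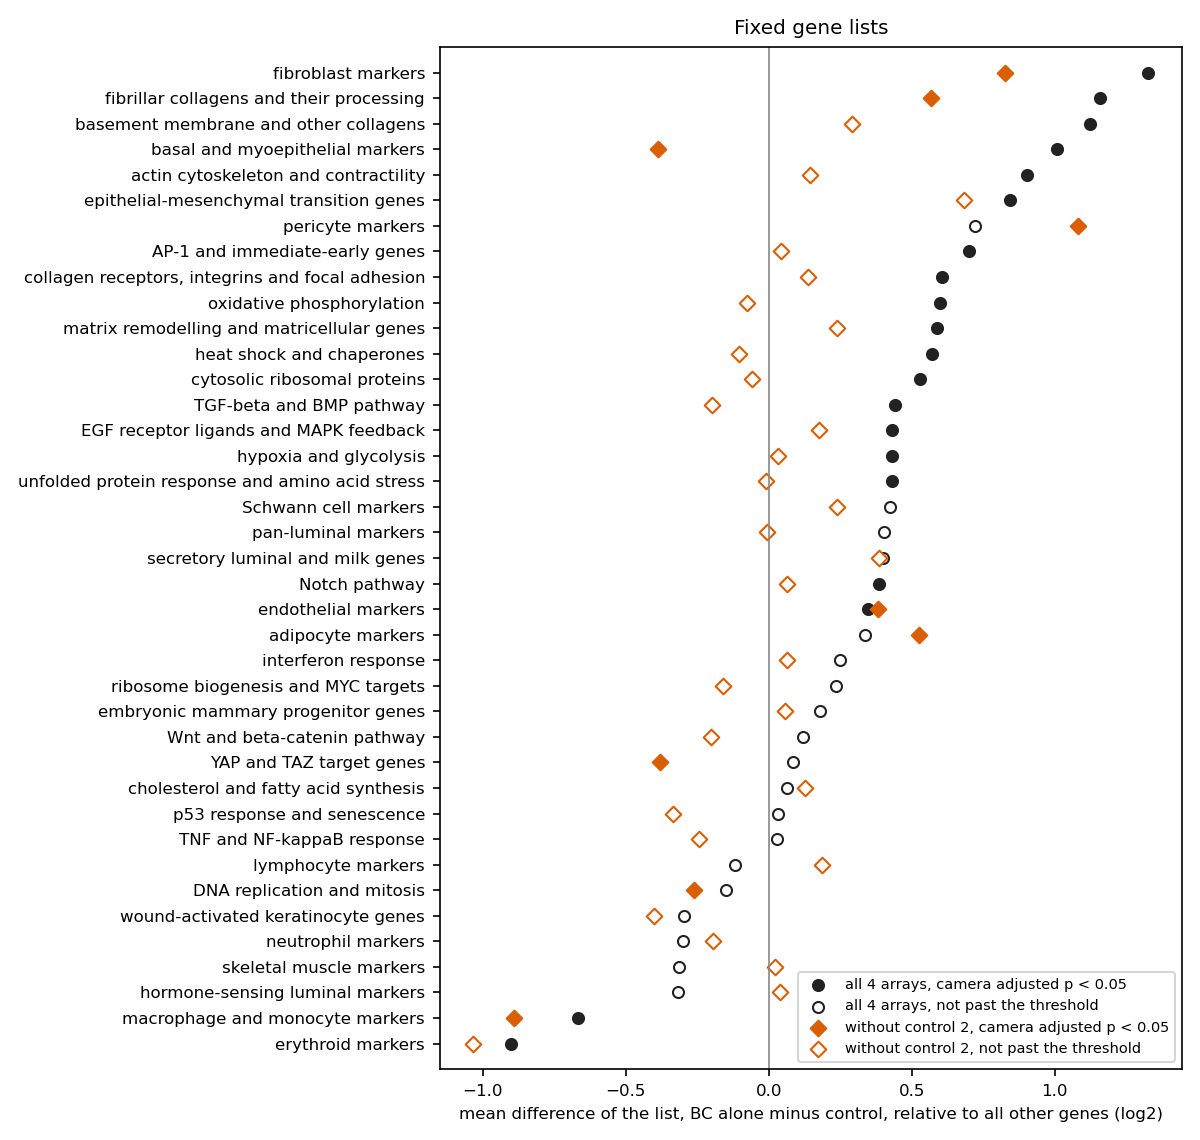
Mean log2 difference of each of the 39 gene lists, BC alone minus control, relative to all other genes. Black circles use all 4 arrays and orange diamonds leave out control replicate 2, and filled symbols passed an adjusted p of 0.05 in camera with a preset correlation. Fibroblast markers lie at 1.33 and 0.83, and the basal list at 1.01 and -0.39.

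Basal keratins and p63 were higher in BC alone on average, but only because of control replicate 2. Krt14 had 10.02 ± 0.30 in BC alone and 8.64 ± 2.62 in the control (SD, n = 2), the control arrays being at 10.49 and 6.78. Trp63, the basal transcription factor p63, had 8.75 ± 0.01 against 7.01 ± 2.55, from 8.81 and 5.20. The basal genes Tcf4, Myh11, Cxcl14 and Cdh3 differed by 0.57, 2.34, 2.10 and 1.34 over all arrays, and by 0.72, 0.29, 0.10 and 0.04 against control replicate 1 alone. Of 19 basal markers, 16 had a higher mean, at 1.01 (adjusted p = 0.0075, and adjusted p = 0.68 with an estimated correlation). Without control replicate 2 the direction turned, with 15 of 19 lower at -0.39 (adjusted p = 0.028), and without control replicate 1 it was 2.40. With an estimated correlation these gave adjusted p = 0.72 and 0.57. The call was also lost under the 3 other scalings, after another quantile normalization at 0.89 (adjusted p = 0.071), after median centring at an unchanged 1.01 (adjusted p = 0.061) and after cyclic loess at 0.62 (adjusted p = 0.11). Members past the threshold numbered 0 over all genes and 0 adjusted over the list alone.

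The luminal keratin genes Krt8 and Krt18 had 10.36 ± 0.08 and 9.5 ± 0.25 in BC alone, against 9.08 ± 1.53 and 8.73 ± 1.34 in the control (SD, n = 2). On control replicate 1 they had 10.16 and 9.67. The luminal regulator Gata3 had 6.69 ± 0.23 against 5.38 ± 0.46, and Muc1 and Prom1 differed by 1.17 and 1.26, but by 0.65 and 0.33 without BC alone replicate 1. Of 17 pan-luminal markers 13 had a higher mean, at 0.40 (adjusted p = 0.053), turning to -0.01 without control replicate 2, -0.03 after another quantile normalization and -0.07 after cyclic loess. That list passed without control replicate 1, at 0.81 (adjusted p = 0.019), and without BC alone replicate 2, at 0.44 (adjusted p = 0.014), and with the mean of a gene's probe sets, at 0.37 (adjusted p = 0.037), and 5 of 14 alternatives passed in all. With an estimated correlation those 3 fits gave adjusted p = 0.57, 0.78 and 0.61. Esr1, the estrogen receptor, had 8.66 ± 0.75 in BC alone and 6.60 ± 0.17 in the control, and Tbx3 differed by 1.02, and by 0.65 without BC alone replicate 1. Another Tbx3 probe set, with a mean of 6.28 against 6.52, differed by -0.51. Of the hormone-sensing luminal markers 12 of 14 had a lower mean all the same, at -0.32 (adjusted p = 0.24), among them Stc2 at -1.25 and Foxa1 at -1.26. Foxa1 and Stc2 differed by 0.025 and -0.715 against control replicate 1 alone, and the list turned to 0.04 without control replicate 2. Stc2 differed by -2.02 without BC alone replicate 1 and -0.47 without BC alone replicate 2. The hormone-sensing list was at -0.50 without BC alone replicate 1. It passed in camera without the dimmer genes, at -0.555 (adjusted p = 0.042, and adjusted p = 0.82 with an estimated correlation). The secretory and milk genes gave 0.40 (adjusted p = 0.12), with Wfdc18 at 1.46, Glycam1 at -2.27, Ltf at -1.32 and Csn1s2a at 2.02. Against control replicate 1 alone Glycam1 and Ltf differed by -1.10 and -0.465, and Csn1s2a by 3.48 and 0.55 without BC alone replicates 1 and 2. That list passed without BC alone replicate 1, at 1.09 (adjusted p = 1.7e-10, and adjusted p = 0.70 with an estimated correlation), and was at -0.29 without BC alone replicate 2. Adjusted over the list alone, 0 members of these 3 lists passed, as over all genes.

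Macrophage and monocyte genes were lower in BC alone. The protease gene Ctss had 5.88 ± 0.38 against 7.25 ± 0.22, Laptm5 5.07 ± 0.26 against 6.20 ± 0.44, Lyz2, lysozyme, 6.53 ± 0.57 against 7.58 ± 0.17 and Cd74, the invariant chain of antigen presentation, 6.46 ± 0.66 against 7.81 ± 0.78 (SD, n = 2). Without BC alone replicate 1 Lyz2 and Cd74 differed by -0.65 and -0.885, and without control replicate 1 Cd74 by -0.795. Of 18 members, 15 had a lower mean and 10 were below both controls on both BC alone arrays. The relative mean difference was -0.67 (adjusted p = 4.6e-05, and adjusted p = 0.66 with an estimated correlation), and -0.89 without control replicate 2 (adjusted p = 7.0e-05). The call was lost without BC alone replicate 1, at -0.21 (adjusted p = 0.19), and without control replicate 1, at -0.45 (adjusted p = 0.20), and without BC alone replicate 2 the value was -1.12. No member passed over all genes and 0 adjusted over the list alone.

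Inflammatory genes Il1b, Cxcl2, Tnfrsf1b and Vcam1 of the TNF and NF-kappaB list were lower in BC alone, at -1.60, -0.88, -0.77 and -0.96, with Vcam1 at -0.51 without BC alone replicate 1. The list itself did not pass, with 14 members higher and 10 lower, at 0.03 (adjusted p = 0.96), and its sign turned without control replicate 2, under another quantile normalization and cyclic loess. The wound-activated keratinocyte genes Krt6b, Gjb2 and S100a9 were also lower, at -1.21, -1.11 and -1.20, and Sbsn was higher, at 1.74. Krt6b lay below the median of all probe sets in both groups and was not tested against background. Against control replicate 1 alone S100a9 and Sbsn differed by -1.84 and 2.80, and without control replicate 1 they and Gjb2 by -0.56, 0.68 and -0.71. Of those 18 genes 13 had a lower mean, at -0.30 (adjusted p = 0.053). The list passed after another quantile normalization (adjusted p = 0.048), median centring (0.048) and cyclic loess (0.031), and without BC alone replicate 2 (0.023), with adjusted p = 0.57 or more in each with an estimated correlation. It did not pass without BC alone replicate 1, at -0.22 (adjusted p = 0.20), without control replicate 1, at -0.19 (adjusted p = 0.34), or without control replicate 2, at -0.40 (adjusted p = 0.14). Among erythroid markers, Alas2, the first enzyme of heme synthesis in red cells, had 5.06 ± 0.06 against 6.39 ± 0.25 (SD, n = 2). The globin genes Hba-a1 and Hbb-b2, whose probe sets can also bind near-identical globin transcripts, differed by -1.42 and -1.75, with BC alone replicate 2 at 8.31 and 7.07 and BC alone replicate 1 at 11.09 and 10.70. The 6 erythroid markers gave -0.90 (adjusted p = 0.016, and adjusted p = 0.66 with an estimated correlation). That call was lost without BC alone replicate 2, at -0.36, without control replicate 1, at -0.77, and without control replicate 2, at -1.03, and without BC alone replicate 1 the value was -1.44. Adjusted over the list alone 1 erythroid gene passed and 0 of the TNF and wound lists did, against 0 over all genes.

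Immediate-early genes were higher in BC alone over all arrays. Fos had 11.49 ± 0.08 against 10.52 ± 1.22 and Jun 10.44 ± 0.08 against 9.32 ± 1.60 (SD, n = 2), but on control replicate 1 they had 11.38 and 10.45, and Fos turned to -0.01 under cyclic loess. Nr4a1 and Fosl2 differed by 1.36 and 0.81 and Batf by -0.68, and against control replicate 1 alone by 0.355, 0.40 and -0.465. Of 21 members of that list 19 had a higher mean, at 0.70 (adjusted p = 8.3e-05, and adjusted p = 0.66 with an estimated correlation), and at 0.04 without control replicate 2 (adjusted p = 0.36). Without control replicate 1 it was 1.36, and the call was lost after another quantile normalization, at 0.23, and cyclic loess, at 0.04. YAP and TAZ target genes, which respond to stiffness, did not pass, at 0.09 (adjusted p = 0.85). They turned to -0.38 without control replicate 2, with 15 of 20 lower (adjusted p = 0.0069), and passed the other way without control replicate 1, at 0.55 (adjusted p = 0.045). With an estimated correlation these 2 gave adjusted p = 0.72 and 0.57. They turned to -0.05 after another quantile normalization and to -0.12 after cyclic loess. The target genes Ankrd1 and Nt5e had 3.91 ± 0.08 against 5.17 ± 0.08 and 4.57 ± 0.04 against 5.65 ± 0.60, and Nt5e differed by -0.65 against control replicate 1 alone. Adjusted over the list alone 0 members of either list passed, as over all genes.

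The receptor genes Notch3 and Notch2 differed by 1.64 and 0.82, Egfr and its feedback inhibitor Spry4 by 1.23 and 1.08, and the TGF-beta receptor gene Tgfbr2 by 1.49. Against control replicate 1 alone Egfr, Spry4 and Tgfbr2 differed by 0.735, 0.73 and 0.855, and Notch3 by 1.08 without BC alone replicate 1. Id3, a BMP target, had 7.80 ± 0.19 against 6.36 ± 0.30, and Inhba, the activin subunit, was lower, with 6.33 ± 0.81 against 8.0 ± 0.95 (SD, n = 2), and differed by -1.10 without BC alone replicate 1 and -1.0 without control replicate 1. The Notch list gave 0.39 (adjusted p = 0.031), the EGF receptor list 0.43 (adjusted p = 0.017) and the TGF-beta and BMP list 0.44 (adjusted p = 0.0075), each with adjusted p = 0.66 with an estimated correlation. Without control replicate 2 they gave 0.06, 0.17 and -0.20, none past the threshold, and without control replicate 1 they gave 0.71, 0.69 and 1.08. Without BC alone replicate 1 the Notch list also lost its call, at 0.22, and all 3 lists lost theirs after another quantile normalization, at 0.28, 0.25 and 0.27, after cyclic loess, at 0.23, 0.23 and 0.16, and without the dimmer genes, at 0.38, 0.39 and 0.33. The Notch and EGF receptor lists lost theirs after median centring too, with their values unchanged (adjusted p = 0.074 and 0.077). Means were higher for 10 of 15, 13 of 19 and 17 of 21 members. The amino acid stress genes Asns and Trib3 differed by 1.11 and 0.87, in a list of unfolded protein response genes with 12 of 17 higher at 0.43 (adjusted p = 0.011, and adjusted p = 0.66 with an estimated correlation). That list turned to -0.01 without control replicate 2 and to -0.04 under cyclic loess, lost its call without BC alone replicate 2, at 0.32, and was at 0.87 without control replicate 1. It also lost its call after another quantile normalization, at 0.02, and without the dimmer genes, at 0.17. Adjusted over the list alone 0 members of these 4 lists passed, as over all genes.

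Over all 39 lists, 20 passed in camera with a preset correlation, 18 higher and 2 lower in BC alone, and 0 passed with an estimated correlation, with a smallest adjusted p of 0.655. With limma's fry 0 passed, at a smallest adjusted p of 0.504. Both rest on the 2 residual degrees of freedom of the fit, so they leave undecided whether a list differs. The preset calls may be too confident, since estimated correlations lay above 0.01. They were 0.35 for fibrillar collagens, 0.23 for fibroblast, 0.03 for endothelial and 0.33 for macrophage markers. Without control replicate 2, 9 passed, 5 higher and 4 lower, and 0 with an estimated correlation, at a smallest adjusted p of 0.724. No list passed with an estimated correlation in any other fit without 1 array, under any other scaling, with the mean of a gene's probe sets or without the dimmer genes, the smallest adjusted p being 0.565. Of the lists past both ways at the preset correlation, fibrillar collagens, fibroblast and endothelial markers were higher and macrophage markers lower, and the basal list alone turned its direction.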

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

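Both results here were looked at only after the data had been seen, and no explanation was tested for either. Among the 16139 probe sets without a single gene symbol that no comparison of genes used, with 104 control probe sets of the array left out, 382 were at least 2-fold higher in BC alone without overlap between the groups and 96 were lower. The count came up because these values lie outside the gene comparison and above the control arrays. The higher and lower ones together made up 2.96% of the 16139, against 5.69% among the genes tested. By share, the count was therefore not high. Among genes of that size 84.3% were higher, against 54.4% after another quantile normalization, 56.5% after cyclic loess and 92.0% after median centring. Whether the excess of higher probe sets also depends on the scaling was not tested. Of the 16139 probe sets 0 passed an adjusted p of 0.05 in limma.

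Probe set 1452296_PM_at was the unnamed probe set with the smallest p among those higher in BC alone. Its log2 values were 8.63 and 8.15 in BC alone and 5.35 and 5.60 in the control, a difference of 2.915 ± 0.286 (SE), with an adjusted p of 0.587 in limma.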

How the results depend on the processing

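The count of 0 genes past the threshold stayed 0 under every setting run except an intensity trend, with 97, and the replicate block, with 108 (94 higher, 14 lower). The labels do not say whether arrays of the same replicate number belong together. Their deviations from the group means correlated at -0.018 over genes. That cannot exclude a pairing, since the control arrays differed by an SD of 0.81 and the BC alone arrays by 0.45. The block's gene calls are given only here, but the ranges and counts over 14 alternatives of a list include the block. With the replicate block 23 lists passed. Cyclic loess, and the estimated correlation in fits other than the main one, were chosen after seeing the data, all other settings before. The cause of a change was not tested unless stated. With 2 arrays per group 1 array can decide a value, and signal over background was not used here. Of 107 named genes 11 changed sign under some setting and 42 passed under the trend or the block, and of 39 lists 18 changed sign.

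Genes at least 2-fold different without overlap numbered 972, and 1951 over all probe sets (more rows), 620 with the mean of probe sets, 614 after quantile normalization, 533 after cyclic loess, 2660 at a fold of 1.5 and 62 at a fold of 4. Leaving out 1 array gave 732 to 3824, without control replicates 2 and 1. In 2 arrays against 1, chance separates 66.7% of genes. Without the dimmer genes only 32 of the 39 lists kept enough members to be tested. Lists past the threshold numbered 20, and 13 without the dimmer genes, 9 after quantile normalization, 10 after cyclic loess, 0 with an estimated correlation and 0 with fry, and 9 to 23 leaving out 1 array.

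With the mean of probe sets the TNF list turned to -0.025. Without the dimmer genes, lists turned as follows, none past the threshold: YAP and TAZ targets -0.040, TNF -0.129, cholesterol -0.122, p53 -0.080 and ribosome biogenesis -0.0051. After quantile normalization Itgb1 turned to -0.34, Ddr1 to -0.20 and Piezo1 to -0.44, and so did the lists of pan-luminal markers to -0.029, YAP and TAZ targets -0.047, TNF -0.231, cholesterol -0.170, p53 -0.135, ribosome biogenesis -0.181 and lymphocytes 0.087, none past the threshold. After cyclic loess Itgb1 turned to -0.51, Ddr1 to -0.20, Piezo1 to -0.47 and Fos to -0.012. So did the lists of pan-luminal markers to -0.073, YAP and TAZ targets -0.124, heat shock -0.092, TNF -0.259, hypoxia -0.060, oxidative phosphorylation -0.022, cytosolic ribosomal proteins -0.328, cholesterol -0.117, unfolded protein response -0.040, p53 -0.176, ribosome biogenesis -0.256 and lymphocytes 0.130, of which ribosomal proteins and ribosome biogenesis passed (adjusted p = 2.2e-05 and 0.031).

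Leaving out 1 array turned the sign of these genes, whose lowest and highest values were -0.415 and 3.23 for Krt5, -0.475 and 3.24 for Krt14, -0.06 and 3.55 for Trp63, -0.17 and 1.72 for Krt18, -0.02 and 0.95 for Ddr1, -0.015 and 2.25 for Jun, and -2.55 and 0.025 for Foxa1, each without control replicates 2 or 1. Piezo1 ran from -0.49 to 0.62 and Hbb-b2 from -3.56 to 0.07, without BC alone replicates 1 or 2. No named gene passed in these fits of 3 arrays, where the lone array is assumed to vary like the other group.

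Lists that turned ran, without control replicates 2 or 1, from -0.386 to 2.40 for basal markers, -0.0063 to 0.81 for pan-luminal markers, -0.672 to 0.040 for hormone-sensing markers, -0.381 to 0.553 for YAP and TAZ targets, -0.104 to 1.25 for heat shock, -0.243 to 0.300 for TNF, -0.200 to 0.443 for Wnt, -0.197 to 1.08 for TGF-beta, -0.075 to 1.27 for oxidative phosphorylation, -0.059 to 1.12 for ribosomal proteins, -0.010 to 0.871 for the unfolded protein response, -0.334 to 0.396 for p53, -0.160 to 0.630 for ribosome biogenesis, -0.418 to 0.186 for lymphocytes and -0.649 to 0.021 for skeletal muscle. Secretory and milk genes ran from -0.290 to 1.09 without BC alone replicates 2 or 1.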

Other observations

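Genes of protein synthesis, respiration and the cytoskeleton were higher in BC alone over all 4 arrays, and that rested on control replicate 2. All 43 measured cytosolic ribosomal protein genes had a higher mean, with a relative mean difference of 0.53 log2 (limma's camera, adjusted p = 6.0e-07), and 36 of them had a lower one without control replicate 2, at -0.06. The list turned to -0.33 under cyclic loess (adjusted p = 2.2e-05). Oxidative phosphorylation gave 0.60 with 34 of 35 genes higher (adjusted p = 7.7e-06), and -0.08 without control replicate 2. Actin cytoskeleton genes gave 0.90 with 18 of 18 higher (adjusted p = 3.5e-06), and 0.15 without it, and lost their call under cyclic loess, at 0.27 (adjusted p = 0.081). Hypoxia and glycolysis genes gave 0.43 (adjusted p = 0.0056) and 0.03 without it, and heat shock genes 0.57 (adjusted p = 0.011) and -0.10 without it. Without control replicate 1 the lists, in this order, gave 1.12, 1.27, 1.66, 0.83 and 1.25. Oxidative phosphorylation, hypoxia and heat shock genes also changed sign under cyclic loess, and all but the actin list lost their call after another quantile normalization. Without the dimmer genes the hypoxia and heat shock calls were lost, at 0.27 (adjusted p = 0.12) and 0.32 (adjusted p = 0.20). Each of these 5 calls had adjusted p = 0.66 with an estimated correlation.

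The lists of this paragraph did not pass over all 4 arrays. DNA replication and mitosis genes gave -0.15 (adjusted p = 0.36), and -0.26 without control replicate 2, with 21 of 33 lower (adjusted p = 0.033), and -0.28 without BC alone replicate 2 (adjusted p = 0.033). Embryonic mammary progenitor genes gave 0.18 (adjusted p = 0.63), Wnt pathway genes 0.12 (adjusted p = 0.98, with a median of -0.14), interferon response genes 0.25 (adjusted p = 0.12), p53 response genes 0.03 (adjusted p = 0.98), cholesterol and fatty acid synthesis 0.07 (adjusted p = 0.53) and ribosome biogenesis 0.23 (adjusted p = 0.12). Among other cell types, adipocyte markers gave 0.34 (adjusted p = 0.053), Schwann cell markers 0.43 (adjusted p = 0.12), neutrophil markers -0.30 (adjusted p = 0.14), lymphocyte markers -0.12 (adjusted p = 0.49) and skeletal muscle markers -0.31 (adjusted p = 0.065). Interferon genes passed without BC alone replicate 1, at 0.49 (adjusted p = 0.0042), and gave 0.008 without BC alone replicate 2. Adipocyte markers passed without control replicate 2, at 0.52 (adjusted p = 0.027), and without BC alone replicate 1, at 0.49 (adjusted p = 0.029), as Schwann cell markers did at 0.57 (adjusted p = 0.035), and adipocyte markers passed after median centring (adjusted p = 0.045). Without control replicate 1, ribosome biogenesis passed at 0.63 (adjusted p = 0.0025) and skeletal muscle at -0.65 (adjusted p = 0.0069). Every call in this paragraph had adjusted p = 0.565 or more with an estimated correlation. Of the lists in these first paragraphs, 0 members passed over all genes. Adjusted over the list alone, 2 Schwann cell markers passed and 0 members of the other lists did.

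The tests in the next 3 paragraphs were all chosen after the patterns had been seen, and each list is set against the middle 95% of 10000 random lists of its size matched on expression, a range that covers the choice of genes and not the spread between arrays. On control replicate 2 the range of values was narrower, basal genes were lower and hormone-sensing luminal genes were higher as a list than on the other 3 arrays. Of 14 hormone-sensing genes 10 lay above the mean of those 3 arrays and 4 below it. Esr1 was among the lower ones, with 6.72 against 8.13 and 9.19 in BC alone and 6.48 on control replicate 1. Fibrillar collagens, basement membrane collagens and fibroblast markers were also below their matched ranges on this array, at -2.085, -2.32 and -2.0. Those ranges were -1.28 to -0.62, -1.47 to -0.915 and -1.055 to -0.15. Cytosolic ribosomal proteins, at -1.31, were above theirs of -1.80 to -1.40. All 14 spike-in probe sets were higher there than on any other array, by a median of 0.68 where the other 3 spanned 0.56, so less labelled target is a candidate explanation for the narrow range. It is argued against for the identity genes, since the basal list changed by a median of -3.23 against a matched range of -1.44 to -0.72, and the hormone-sensing list by 0.617 against -0.32 to 0.35, with Cited1 at 9.28 against 5.34 to 6.04, while these lists differed by -0.20 and -0.215 between the BC alone arrays. Luminal cells in place of basal cells among the 50 sorted could do this, but the pan-luminal list changed by -0.84, within its range of -1.41 to -0.70, so that stays open. A biological difference between transplants was not tested.

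Fibrillar collagen genes were higher in BC alone. Control replicate 2 as the whole reason is argued against for these arrays only. The list's median difference from control replicate 1 alone was 0.565, above a matched range of -0.11 to 0.17, while the BC alone arrays differed by -0.23. The list medians of the control arrays, 7.0 and 5.505, lay further apart than 0.565. With 1 control array left, a group difference cannot be told from that array's own sample of cells. A lower share of basal cells could raise markers of all other cell types, and stays open. Against control replicate 1 the basal list was at -0.415 and the endothelial list at 0.32. Pericyte, adipocyte and Schwann cell markers were at 0.52, 0.675 and 0.30. The pan-luminal and hormone-sensing lists, at 0.05 and -0.01, did not rise beyond their ranges of -0.17 to 0.23 and -0.17 to 0.21. The macrophage list, at -0.875, went against it but differed by 0.675 between the BC alone arrays. The erythroid list, at -0.88, also went against it, but its medians on the BC alone arrays were 7.705 and 6.045. More RNA from fibroblasts remains a candidate explanation, since fibroblast markers were at 0.895 against control replicate 1, above -0.16 to 0.22 and past the 0.305 between the BC alone arrays, with Dcn at 10.84 and 11.16 in BC alone and 9.91 and 8.02 in the control, although Col14a1 and Fbln1 were at -0.33 and -0.04. The fibroblast list medians of the control arrays, 6.0 and 4.655, lay further apart than 0.895. None of those 14 markers is in another list, but other cells that make matrix also express several of them, the sort's gate is not stated, and a change in the transplanted cells themselves was not tested.

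Several milk genes were high on 1 array, BC alone replicate 2. Csn2, beta-casein, had 9.18 there against 4.67 on BC alone replicate 1 and 4.79 and 6.92 on the control arrays. Against BC alone replicate 1, Btn1a1 had 10.25 against 6.26, Csn1s2a 9.92 against 6.99 and Lalba, alpha-lactalbumin, 9.48 against 5.91. The luminal progenitor genes Elf5 and Kit had 6.90 against 4.19 and 6.29 against 4.06. On the control arrays Elf5 had 6.01 and 5.37 and Kit 4.90 and 4.32, so both were lowest on BC alone replicate 1. However, Wap had 4.14 on BC alone replicate 2 against 5.89 on control replicate 2, and Csn1s1 7.65 against 8.27 on control replicate 1. The secretory list differed by a median of 0.675 between the BC alone arrays, above a matched range of -0.17 to 0.16. It was not alone, since macrophage markers at 0.675 and fibroblast markers at 0.305 were also above their ranges. The basal, hormone-sensing, endothelial and fibrillar collagen lists were below theirs. More secretory luminal cells among the sorted cells could give the secretory difference, but the pan-luminal list differed by 0.03, within -0.20 to 0.19, which decides nothing. The biological explanation that BC cells transplanted alone had begun to express luminal genes was not tested, and 1 array in 2 shows the pattern.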
